A study of Mus musculus with 4 samples.

How the data were processed

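The series measured poly(A) RNA in tumours taken 1 day after injection of AXT osteosarcoma cells in matrigel into mice, with 1 mock sample and 3 samples of HIF-1alpha knockout lines. Libraries were made with a directional kit, per the labels' protocols. The deposited values are raw counts of reads per Ensembl gene, 1 column per library. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9, featureCounts 1.6.3 and the build GRCm38 were used. Their settings, including strand and the treatment of reads that map to several places, were not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore be split or shared. Columns c11, c15 and c22 hold knockout lines, but which line of the labels each one is was not given in the sources used here, and they were used as 3 libraries of 1 group. No column of another sample was present.

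The table held 55487 genes, and 55227 of the IDs were found in GENCODE M21 for GRCm38, 54907 with identical coordinates. Symbols and coordinates are those of the deposited table. Where several IDs shared a symbol, the symbol stayed with the ID of the highest total count. Pairs of libraries differed in their counts far beyond sampling noise, with a chi-square per gene from 48.3 to 90.3, so no library was a copy of another. The labels do not say whether the tumours of the knockout lines came from separate animals, so p-values measure the spread between these libraries.

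Genes were kept with edgeR's filterByExpr (15706 genes, 99.9% of counts), scaled by TMM and tested with the quasi-likelihood test (robust, 2-sided) of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The single mock library was assumed to vary as the knockout lines do, so the spread rested on 2 residual degrees of freedom and a prior of 3.77. The biological coefficient of variation was 0.442. The SE of a log2 fold change was taken from the F statistic. The median log2 fold change of all tested genes was 0.05.

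The comparisons, 30 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested genes (27 lists) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. No list called by camera held with an estimated correlation, and none had a fry adjusted p under 0.05. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so it had little power here. For the stress response list the estimate was -0.0035, under the preset 0.01, and the call was still lost. For that list the lost call therefore does not show that correlation between genes had produced it. Most other called lists had estimates above the preset. These were 0.219 for glycolysis, 0.0833 for hypoxia response, 0.196 for cell cycle, 0.491 for erythroid and 0.671 for macrophage markers. Estimates were 0.71 for interferon response and 0.88 for muscle markers. For such lists, correlation between genes may have contributed to the call at the preset. For each knockout library, a list's median log2 ratio to mock (CPM with 0.5 added) was ranked among 10000 random lists matched on expression in 20 bins. Genes of the random lists were drawn independently of each other. A list whose genes vary together therefore reaches an extreme rank more easily. The MYC and ribosome biogenesis list lay below all random lists in c11 and c22, and at percentile 87.08 in c15. Such ranks are therefore no test of the knockout. The naming rule took Hif1a, up to 10 genes in each direction that passed the threshold with a mean of at least 5 CPM and all 3 knockout libraries on the same side of mock, filled to 10 with the smallest unadjusted p as values without a call, up to 4 members of each list with a mean of at least 1 CPM (the 2 highest and 2 lowest) and the 10 genes with the widest range among knockout libraries. Predicted genes, Rik clones and pseudogenes were left out of it. Vegfa, other list members that passed over the list alone, genes of Gene Ontology processes and the genes of chromosome 5 were named after their values were seen. The values of 1 list member are not reported.

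The test was checked on simulated data with known changes, 1 mock against 3 knockout libraries. At the dispersion estimated from these data (15276 genes), 41 of 100 genes changed 4-fold and 92 of 100 changed 16-fold were recovered, with 28 false calls. A glycolysis list set at a log2 change of -1 was the only list called. Genes were simulated independently of each other, so list calls were not checked for genes that vary together. At a lower dispersion (15222 genes), 91 and 98 of 100 were recovered, with 17 false calls. In both simulations false calls made up a larger share of the calls than the threshold for the adjusted p allows. The test was therefore not shown to hold its error rate with 1 mock library. In the data, Ankrd37 (49.7-fold lower), Magel2 (91.3-fold lower) and Gadd45a (25.9-fold higher) did not pass. The simulated recovery at 16-fold may therefore overstate the power here.

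Alternatives were other scalings (RLE, upper quartile, total counts, and TMM without markers, mitochondrial and the 50 most abundant genes), other filters, DESeq2 1.42.0, limma-voom, edgeR's legacy fit, the fit without robust estimation, a test against a log2 fold change of 1, leaving out each knockout library, and sums of pairs of knockout libraries. Leaving out mock was not possible, since it was the only library of its group.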

Results

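Poly(A) RNA was sequenced from tumours formed by AXT cells, a mouse osteosarcoma line derived from bone marrow stromal cells that overexpress c-MYC. The cells carried either a mock treatment or a knockout of HIF-1alpha, the oxygen-regulated transcription factor encoded by Hif1a. The cells were injected in matrigel into immunodeficient C57BL/6scid mice, and the tumours were taken after 1 day. There was 1 mock library and there were 3 knockout libraries, named c11, c15 and c22 in the deposited table. Total counts were 12383719 in mock, 12910058 in c11, 13193264 in c15 and 13081007 in c22. A count of 0 allowed up to 0.242 CPM in mock and up to 0.228, 0.229 and 0.233 CPM in the knockout libraries, for counting error only. Errors below are the SD over the 3 knockout libraries or the SE of the fitted log2 fold change (knockout minus mock). The mock library had no replicate.

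Hif1a itself (chromosome 12, 73901375 to 73947530, GRCm38, plus strand) was measured first. Its level was 107 CPM in mock, 103 CPM in c11, 98.9 CPM in c15 and 22.7 CPM in c22. The fitted log2 fold change was -0.52 (SE 0.78, edgeR adjusted p = 1). RNA from the locus was therefore at about the mock level in c11 and c15 and lower in c22, by a log2 ratio of -2.21. A gene-level count covers all exons and does not show whether an intact protein was made, so it did not check the labels of c11 and c15.

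The comparison of the 3 knockout lines with mock asked which transcripts depended on HIF-1alpha in the first day after implantation. The 10 genes named on the lower side, those with the smallest p, included 4 members of the fixed hypoxia and glycolysis lists: the mitophagy receptor gene Bnip3, the HIF target Ankrd37, the phosphofructokinase gene Pfkl and the transcriptional repressor gene Bhlhe40. Bnip3 (chromosome 7, 138890836 to 138909519) was at 468 CPM in mock and 34.0 ± 5.26 CPM (SD, n = 3) in the knockout libraries, a 13.8-fold difference. Ankrd37 (chromosome 8, 45996902 to 46005707) was at 65.2 CPM in mock and 1.30 ± 0.79 CPM in the knockout libraries. Of the 10 genes named on the higher side, 3 were members of the fixed stress response list: Creld2, Hyou1 and Sdf2l1. Ppp1r15a, which encodes the stress-induced regulatory subunit of the eIF2alpha phosphatase, was at 18.5 CPM in mock and 105 ± 7.83 CPM in the knockout libraries, and Gadd45a was at 1.77 CPM against 46.2 ± 15.6 CPM.

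Across 15706 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05 as higher and 1 as lower in the knockout libraries. At an unadjusted p under 0.05 there were 176 higher and 402 lower genes, against 785 that chance gives in both directions together. DESeq2 called 51 genes higher and 67 lower, including 19 of the 20 genes named by rule. Those 20 had been chosen by small edgeR p in the same libraries, so this is no separate check. With limma-voom, 0 were called in either direction, and 566 genes had an unadjusted p under 0.05. With each library taken in turn as the lone one against the other 3, edgeR called 1 gene for mock, 3 for c11, 1 for c15 and 0 for c22. At an unadjusted p under 0.05 there were 578, 610, 760 and 1163 genes. Mock had the fewest genes at that unadjusted p, and only c22 had fewer called genes. In the splits of a knockout library mock was among the other 3, so the splits are not alike. The 1 gene that fell in edgeR was Xlr3c (chromosome X, 73254540 to 73265390), with 130 counts in mock and 1 count in each knockout library. It lay outside the naming rule and was singled out after its values were seen. Its ratio of mock to knockout was 137, with an exact 95% counting interval of 45.8 to 672, and the fitted log2 fold change was -6.92 (SE 0.60, edgeR adjusted p = 0.0178). Xlr3c has near-identical copies on the X chromosome that can share reads, so its level is uncertain, and the call was lost when any 1 knockout library was left out, with 0 genes called each time.

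The other genes named on the lower side were Dbf4, Lrp2bp, Magel2, Rundc3b, Abcb1a and Arrb1, and none of the 10 passed edgeR over all genes. Dbf4, which encodes the activating subunit of the replication kinase Cdc7, was at 986 CPM in mock and 161 ± 4.56 CPM in the knockout libraries (log2 fold change -2.62, SE 0.24, edgeR adjusted p = 0.114). Magel2 was at 24.2 CPM in mock and 0.25 ± 0.44 CPM in the knockout libraries, where c11 and c22 had 0 counts. Arrb1, the gene of beta-arrestin 1, was at 78.2 CPM against 12.6 ± 2.45 CPM. Lrp2bp was at 31.8 CPM against 1.15 ± 0.52 CPM, and its annotated span overlaps that of Ankrd37, so reads of the 2 genes may not have been kept apart. Bnip3 had the smallest adjusted p of the 10, 0.0872 (and 0.0328 with no filter), and Pfkl, Arrb1 and Bhlhe40 the largest, 0.218.

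The remaining genes named on the higher side were Creld2, Hyou1, Sdf2l1, Manf, Lamb1, Angptl6, Ogn and Avil, with adjusted p from 0.248 for Ppp1r15a to 0.356 for Avil. Creld2, Hyou1, Sdf2l1 and Manf encode proteins of the endoplasmic reticulum. Hyou1, a chaperone gene, was at 167 CPM in mock and 656 ± 52.5 CPM in the knockout libraries, and Manf was at 108 CPM against 415 ± 48.7 CPM. Lamb1, the laminin beta 1 gene, was at 12.4 CPM against 97.9 ± 28.2 CPM, and Ogn, which encodes a matrix proteoglycan, was at 11.8 CPM against 85.4 ± 27.6 CPM. Avil was at 2.34 CPM against 61.6 ± 29.2 CPM.

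Glycolysis genes, textbook targets of HIF-1, were lower in the knockout libraries as a group. Of 21 genes tested, 12 fell and 0 rose, adjusted over the list alone, while 0 passed edgeR over all genes and 6 passed DESeq2, and 16 were below mock in all 3 knockout libraries. Those that fell covered most steps from glucose uptake to lactate: Slc2a1, Hk2, Gpi1, Pfkl, Pfkp, Aldoa, Tpi1, Gapdh, Pgk1, Pgam1, Pkm and Ldha. Pfkl fell from 411 to 72.0 ± 17.3 CPM (SD, n = 3; log2 fold change -2.51, SE 0.33), and Ldha, the lactate dehydrogenase gene, from 3863 to 1045 ± 496 CPM. Pgk1 fell from 2205 to 557 ± 110 CPM. Pdk1, which restrains pyruvate entry into mitochondria, was at 393 CPM in mock and 69.5 ± 52.4 CPM in the knockout libraries and did not pass (adjusted p over the list alone 0.058), and the regulatory enzyme genes Pfkfb3 and Pfkfb4 were near the mock level, with log2 fold changes of 0.39 (SE 0.52) and 0.01 (SE 0.57). Gapdh was counted at only 64.6 CPM in mock, and its many processed pseudogenes make that level uncertain.

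The list's median log2 fold change was -1.34, a 2.52-fold difference. Medians were -1.81 in c11, -1.12 in c15 and -1.51 in c22, each below all of 10000 random lists matched on expression. Random genes were drawn independently, so these ranks do not allow for genes that vary together. The 3 ratios share the mock library and are not independent: of all 15706 tested genes, 3486 were below mock and 3363 above mock in all 3 knockout libraries. The camera test gave an adjusted p of 1.05e-36 with its preset correlation, and adjusted p = 0.234 with an estimated correlation. Markers of skeletal muscle (median -3.52), erythroid cells (median -2.83) and macrophages (median -0.68) were lower in the knockout libraries as well.

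The hypoxia response genes outside glycolysis moved the same way. Of 33 tested, 18 fell and 0 rose, adjusted over the list alone, 0 passed edgeR over all genes and 12 passed DESeq2, and 25 were below mock in all 3 knockout libraries. Egln3, an oxygen-sensing prolyl hydroxylase gene, fell from 97.4 to 3.79 ± 4.22 CPM (log2 fold change -4.69, SE 0.88), and Car9, the carbonic anhydrase gene often used as a hypoxia marker, fell from 16.2 to 0.78 ± 1.21 CPM. Ndrg1 fell from 421 to 80.8 ± 34.4 CPM, and the peptide hormone genes Apln and Adm fell from 58.9 to 7.45 ± 5.33 CPM and from 4.84 to 0.44 ± 0.24 CPM. Vegfa, a classic HIF target, was at 113 CPM in mock and at 104, 66.6 and 144 CPM in c11, c15 and c22 and did not pass. Plod1 and Ppfia4 had log2 fold changes of 0.05 (SE 0.47) and 0.59 (SE 0.96).

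The median of the hypoxia response list was -1.49, a 2.81-fold difference, and medians of -1.36, -1.44 and -1.39 in c11, c15 and c22 lay below all of 10000 random lists. Camera gave an adjusted p of 1.09e-49, and adjusted p = 0.161 with an estimated correlation. The same markers of muscle, erythroid cells and macrophages were lower beside it. Among 10 HIF pathway components, 2 fell, adjusted over the list alone: Egln3 and Egln1, both also in the hypoxia list. The partner subunit gene Arnt was at 85.7 CPM in mock and 129 ± 28.1 CPM in the knockout libraries, and Arnt2 was at 0.40 CPM against 5.81, 0.46 and 0.47 CPM. The median of the components was -0.17 (camera adjusted p = 0.00507, and adjusted p = 0.351 with an estimated correlation). It was -0.32 without c11, and the call was lost without c15 (adjusted p = 0.0508) and with no filter (0.077).

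**Figure D1:**
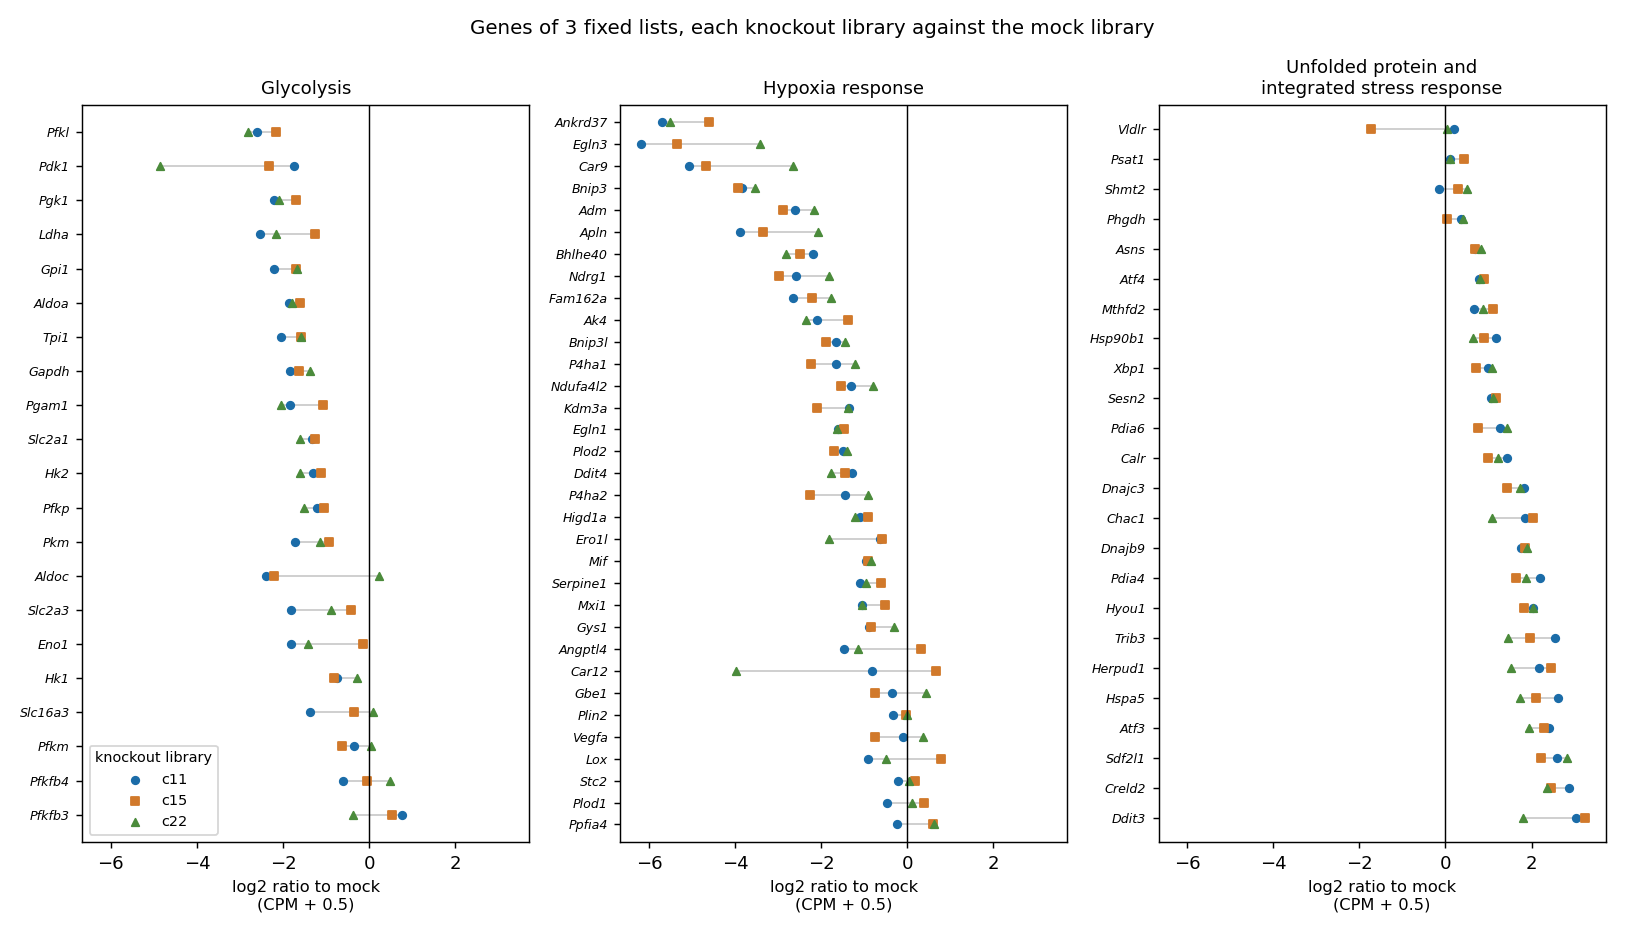
Each point is the log2 ratio of 1 knockout library to the mock library (TMM-scaled CPM with 0.5 added), for every tested gene of the glycolysis, hypoxia response and stress response lists. Lines join the 3 libraries of a gene; 16 of 21 glycolysis genes and 25 of 33 hypoxia response genes lie left of 0 in all 3 libraries, and 22 of 24 stress response genes lie right of 0.

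Genes of the unfolded protein response and the integrated stress response were higher in the knockout libraries. Of 24 tested, 19 rose and 0 fell, adjusted over the list alone, 0 passed edgeR over all genes and 11 passed DESeq2, and 22 were above mock in all 3 knockout libraries. The endoplasmic reticulum chaperone gene Hspa5 rose from 657 to 3010 ± 932 CPM (SD, n = 3; log2 fold change 2.20, SE 0.45), and its partners Sdf2l1 and Creld2 rose from 29.4 to 178 ± 36.4 CPM and from 29.8 to 180 ± 35.4 CPM. The stress transcription factor gene Ddit3 rose from 21.3 to 153 ± 69.2 CPM, Atf3 from 6.45 to 32.2 ± 5.30 CPM and Atf4 from 306 to 546 ± 25.2 CPM. The serine synthesis gene Psat1 (log2 fold change 0.22, SE 0.30) and the lipoprotein receptor gene Vldlr (log2 fold change -0.28, SE 0.71) did not pass. The list's median was 1.45, a 2.72-fold difference, with medians of 1.59, 1.30 and 1.32 in c11, c15 and c22, each above all of 10000 random lists. Camera gave an adjusted p of 1.27e-40, and adjusted p = 0.118 with an estimated correlation. Markers of muscle (-3.52), erythroid cells (-2.83) and macrophages (-0.68) moved the other way in the same comparison.

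Respiratory gene groups showed no shift past the test. None of 33 nuclear-encoded oxidative phosphorylation genes passed (median -0.03, or -0.06 without c22; camera adjusted p = 0.896), nor did any of 22 tricarboxylic acid cycle and pyruvate entry genes (median 0.05, or 0.12 without c11 or c15; camera adjusted p = 0.379) or of 12 mitochondrial genome transcripts (median -0.08, camera adjusted p = 0.896). The malate dehydrogenase gene Mdh2 was at 409 CPM in mock and 580 ± 53.9 CPM in the knockout libraries, and the fumarase gene Fh1 was at 221 CPM against 182 ± 40.0 CPM. Mitochondrial genome transcripts made up 2.04% of counts in mock and 2.08%, 1.86% and 2.62% in c11, c15 and c22.

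Cell cycle genes were slightly lower as a group, with 16 of 29 below mock in all 3 knockout libraries and a median of -0.30 (camera adjusted p = 0.0013, and adjusted p = 0.541 with an estimated correlation). Without c11 the median was -0.18 and the call was lost (adjusted p = 0.0586). No single gene of that list passed, and the replication clamp gene Pcna was at 369 CPM in mock and 258 ± 11.9 CPM in the knockout libraries. Osteoblast lineage genes had a median of -0.79 (camera adjusted p = 3.09e-05, and adjusted p = 0.351 with an estimated correlation), from -0.49 without c11 to -1.08 without c15. Markers of host fibroblasts (median -0.80), muscle (-3.52) and erythroid cells (-2.83) were lower beside it. Of 15 tested, 1 fell, adjusted over the list alone: Msx2, a homeobox gene, from 5.73 to 0.23 ± 0.23 CPM. Dmp1, a matrix protein gene of osteocytes, was at 75.4 CPM in mock and at 0.61, 16.5 and 9.47 CPM in c11, c15 and c22. MYC and ribosome biogenesis genes had a median of -0.23 (19 tested, camera adjusted p = 0.0514), from -0.09 without c22 to -0.59 without c15, where camera called the list lower (adjusted p = 2.58e-06). It was also called with upper quartile scaling (0.0438), a mean of at least 1 CPM (0.0325), limma-voom (0.0278), and c15 summed with c22 (0.00838) or c11 (0.00392). Myc itself was at 3.47 CPM in mock and 14.8, 24.2 and 3.80 CPM in c11, c15 and c22, and whether an introduced copy was counted at this gene was not given in the sources used here.

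Of 15 p53 targets and apoptosis genes, 1 rose, adjusted over the list alone: Gdf15, a secreted stress cytokine gene, from 2.34 to 15.8 ± 1.61 CPM (log2 fold change 2.75, SE 0.55). Cdkn1a was at 84.4 CPM in mock and 57.8 ± 19.5 CPM in the knockout libraries, and the median of that list was 0.27 (camera adjusted p = 0.216), and 0.11 without c15. Among 15 immediate early and heat shock genes, Atf3 rose, and Hspb1 and Ier3 fell from 6.70 to 0.36 ± 0.31 CPM and from 90.0 to 20.8 ± 6.24 CPM, adjusted over the list alone. The median was -0.73 (camera adjusted p = 1.15e-04, and adjusted p = 0.541 with an estimated correlation), and -1.19 without c15. Macrophage (-0.68), host fibroblast (-0.80), muscle (-3.52) and erythroid (-2.83) markers were lower beside this list and the cell cycle list. NRF2 and iron antioxidant genes had a median of 0.46 (camera adjusted p = 0.00287, and adjusted p = 0.351 with an estimated correlation), 0.26 without c11, with 0 of 15 genes past the test. Osgin1 was at 2.02 CPM in mock and 10.7 ± 1.64 CPM in the knockout libraries, and the transferrin receptor gene Tfrc was at 242 CPM against 135 ± 80.1 CPM.

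Angiogenic ligands went both ways. Of 14 tested, 1 rose and 3 fell, adjusted over the list alone: Pgf, the placental growth factor gene, rose from 0.48 to 4.40 ± 0.96 CPM, and Adm, Apln and the endothelin gene Edn1 fell, Edn1 from 1.37 to 0.23 ± 0.08 CPM. Library medians of the list were -0.40 in c11, -0.19 in c15 and 0.06 in c22. The fitted median was 0.13, and 0.05 without c15, while camera pointed lower (camera adjusted p = 0.197). None of 24 extracellular matrix genes passed (median 0.01, camera adjusted p = 0.871), and Col6a1 ranged from 9.35 CPM in c15 to 263 CPM in c11. None of 16 cholesterol synthesis genes passed (median 0.16, camera adjusted p = 0.176, and 0.0352 without c11). None of 15 chemokine and cytokine genes passed, and 1 of them had 0 counts in mock. Library medians, with 0.5 CPM added, were -0.03 in c11, 0.70 in c15 and 0.63 in c22. The fitted median was 1.07, above all 3 (camera adjusted p = 0.164). The median was 0.10 without c15 and 1.27 without c11, where camera called the list higher (adjusted p = 5.22e-04), as it did with c11 and c22 summed (0.0253). The monocyte chemoattractant gene Ccl2 was at 61.0 CPM in mock and 31.3 ± 7.72 CPM in the knockout libraries. Interferon response genes had a median of 1.04 (17 tested, 0 passed, camera adjusted p = 3.83e-04, and adjusted p = 0.585 with an estimated correlation), and that median differed between libraries: 0.08 in c11, 0.65 in c15 and 1.46 in c22. Without c22 it was 0.62 and the call was lost (adjusted p = 0.0564). Macrophage (-0.68), host fibroblast (-0.80), muscle (-3.52) and erythroid (-2.83) markers moved the other way beside the interferon and NRF2 lists.

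**Figure D2:**
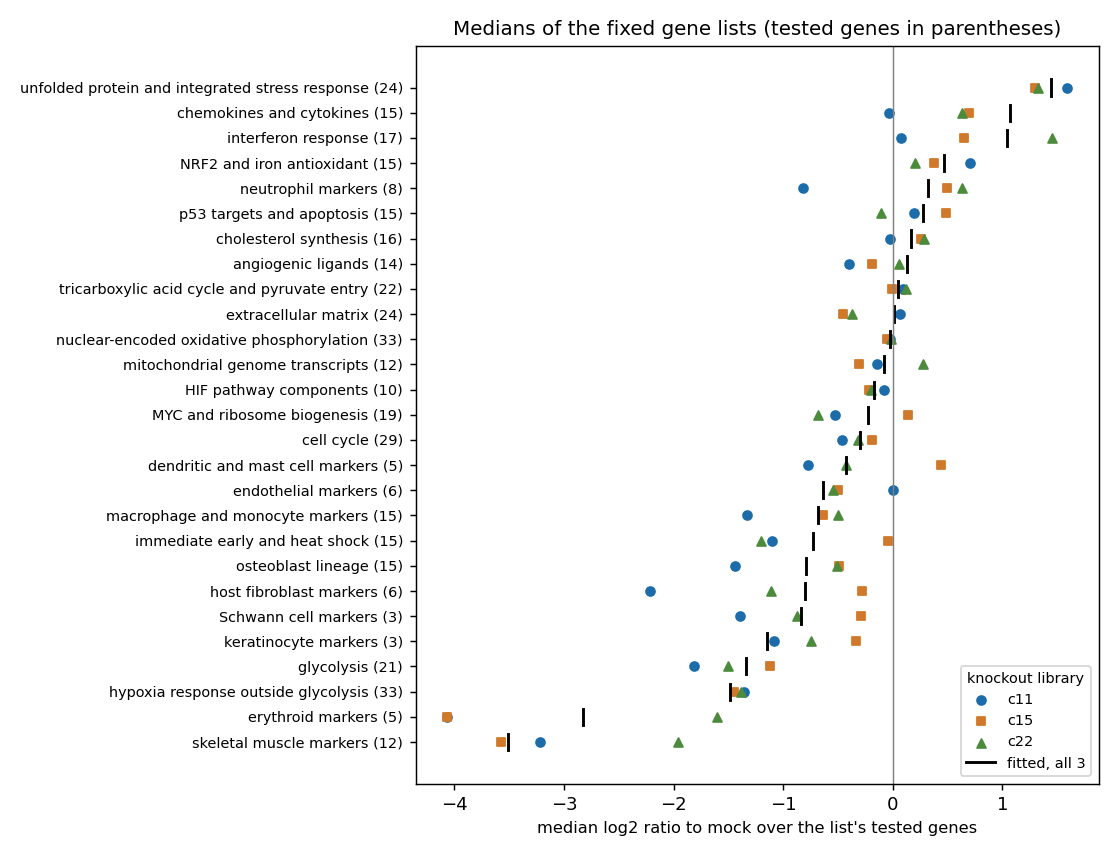
Points are the median log2 ratio of each knockout library to the mock library over the tested genes of each fixed list with at least 3 such genes, and black bars are the median fitted log2 fold change. The glycolysis, hypoxia response, muscle and erythroid lists lie below -1 and the stress response list above 1 in all 3 libraries.

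Markers of other cell types were mostly higher in the mock tumour. Of 12 skeletal muscle genes, 10 fell in the knockout libraries, adjusted over the list alone, and all 12 were below mock in all 3 libraries: Myh4, a fast myosin gene, was at 31.3 CPM in mock and at 0, 0 and 5.12 CPM in c11, c15 and c22. The muscle median was -3.52 (camera adjusted p = 4.73e-18, and adjusted p = 0.351 with an estimated correlation). The medians were -3.22 in c11, -3.58 in c15 and -1.96 in c22, and -6.23 in the fit without c22. Erythroid markers had a median of -2.83 (5 tested; camera adjusted p = 5.67e-07, and adjusted p = 0.351 with an estimated correlation), and of -5.37 without c22. The haem synthesis gene Alas2 fell, adjusted over the list alone, from 3.71 to 0.61 ± 0.23 CPM, and the globin gene Hba-a1 was at 46.0 CPM in mock and 0.08, 1.52 and 11.5 CPM in the knockout libraries. Globin genes have near-identical copies, so their single levels are uncertain. Differences of this size were not particular to mock. With c11, c15 and c22 as the lone library, muscle medians (the others minus the lone library) were 4.781, 6.117 and 0.698. Erythroid medians were 7.831, 3.636 and 0.293. Mock was among the others in those splits.

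Macrophage and monocyte markers had a median of -0.68 (15 tested; camera adjusted p = 1.23e-06, and adjusted p = 0.541 with an estimated correlation), and no single gene passed. Lyz2, the lysozyme gene of myeloid cells, was at 553 CPM in mock and 200 ± 65.6 CPM in the knockout libraries, and the mannose receptor gene Mrc1 was at 62.9 CPM against 21.2 ± 5.75 CPM. Host fibroblast markers had a median of -0.80 (6 tested, 0 passed, camera adjusted p = 0.0154, and adjusted p = 0.558 with an estimated correlation), from -0.41 without c11 to -1.71 without c15. The call was lost without c11 (adjusted p = 0.168), with no filter (0.114) and with c11 and c22 summed (0.0582). Schwann cell markers had a median of -0.83 (3 tested, camera adjusted p = 0.0332, and adjusted p = 0.414 with an estimated correlation), a call lost without c11 (0.0597) or c15 (0.124), with DESeq2 (0.115) or limma-voom (0.0619), and with c15 summed with c22 (0.0697) or c11 (0.0616). With no filter the median was -2.83 (camera adjusted p = 0.00309).

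Neutrophil markers did not pass (8 tested, median 0.32, camera adjusted p = 0.896), and neither did dendritic and mast cell markers (5 tested, median -0.43, camera adjusted p = 0.419), endothelial markers (6 tested, median -0.63, camera adjusted p = 0.486, and 0.0183 with no filter) or keratinocyte markers (3 tested, median -1.15, camera adjusted p = 0.197). None of the 11 lymphoid and NK cell markers had enough counts to be tested. Only 2 adipocyte markers were tested: Car3 was at 23.6 CPM in mock and 6.49 ± 6.86 CPM in the knockout libraries, and Lpl was at 46.3 CPM against 53.9 ± 34.5 CPM. The X-inactivation transcript Xist was at 22.8 CPM in mock and 12.1 ± 7.60 CPM in the knockout libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 4 libraries.

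Genes of 1 stretch of chromosome 5 were lower in the knockout libraries side by side; the stretch was singled out after its values were seen. It ran from Sri to Gm43719 (8046078 to 13606233). Between 9330182L06Rik, which ends at 9481825, and Sema3d, which starts at 12383385, no gene had a mean of at least 1 CPM. In all the stretch held 18 genes with such a mean. Of these, 16 were at least 2-fold below mock in all 3 knockout libraries. Its ends were set from the same values. The window of 11 neighbouring genes furthest from 0 was extended over genes at least 2-fold lower in the fit. The share of lower genes thus follows largely from how the stretch was bounded. Besides Dbf4, Rundc3b and Abcb1a from the naming rule, it held the drug efflux pump gene Abcb1b, at 537 CPM in mock and 64.2 ± 44.9 CPM in the knockout libraries, the carnitine octanoyltransferase gene Crot, at 334 CPM against 56.0 ± 21.6 CPM, and the guidance cue gene Sema3d, at 94.0 CPM against 10.9 ± 4.56 CPM. Upstream of it, Cldn12 (5489537 to 5514958) and Gtpbp10 (5537454 to 5559538) had log2 fold changes of -1.57 (SE 0.28) and -1.94 (SE 0.34). Both were also at least 2-fold below mock in all 3 libraries and passed DESeq2 (adjusted p = 0.00954 and 0.00562). Between them and Sri, Cfap69 was at -1.23 (SE 0.94), Steap2 at -1.07 (SE 0.35) and Steap1 at 0.04 (SE 0.32). Gm15459 and Tubb4b-ps1 in that gap were at -0.52 (SE 0.33) and -0.465 (SE 0.74). Inside the stretch, Dmtf1 had a log2 fold change of -0.70 (SE 0.28) and Gm7332 of -0.26 (SE 0.58). Abcb1a, Abcb1b and Abcb4 are close paralogs, and Tmem243 overlaps Dmtf1, so single levels of these genes are uncertain. None of the 18 genes passed edgeR over all genes, where the adjusted p of Dbf4, 0.114, was the smallest, and 11 passed DESeq2.

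**Figure D3:**
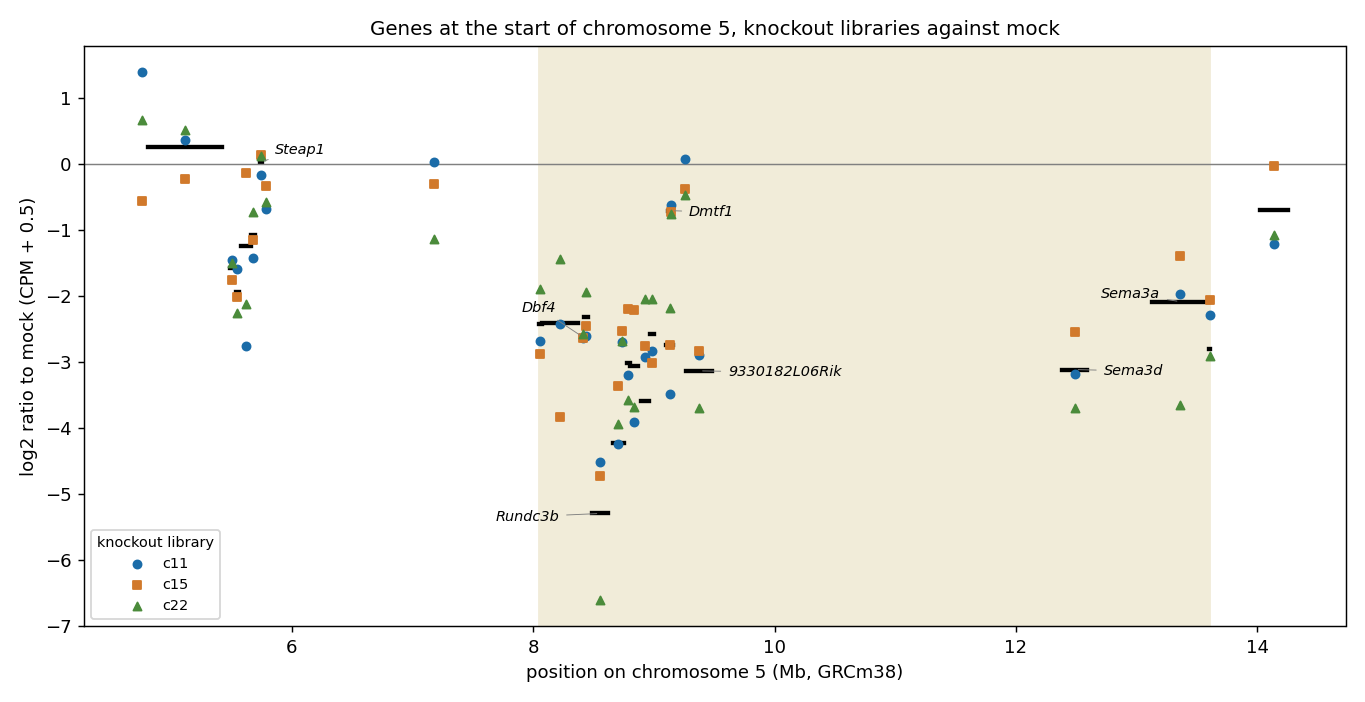
Points are log2 ratios of each knockout library to the mock library (CPM with 0.5 added) for genes with a mean of at least 1 CPM, placed at the gene's midpoint on chromosome 5 (Mb, GRCm38), and black bars span each gene at its fitted log2 fold change. The shaded stretch, whose ends were set from these fold changes, holds 18 genes. Of these, 16 are at least 2-fold lower than mock in all 3 libraries, while Dmtf1 lies at -0.70.

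The 3 knockout libraries differed from each other in many genes. Of 11285 genes with a mean of at least 5 CPM over the knockout libraries, 595 (5.27%) differed at least 4-fold between the highest and the lowest library. The library furthest from the other two was c15 for 285 of these, c22 for 167 and c11 for 143. The widest ranges were nearly on or off: Tenm3, a teneurin adhesion gene, was at 119 CPM in c15 and 0 in c11 and c22, the prostaglandin-degrading enzyme gene Hpgd was at 102 CPM in c15, 1.07 in c11 and 0 in c22, and the transcription factor gene Sox11 was at 86.2 CPM in c11 and 0 in c15 and c22. Ncam1, a neural cell adhesion gene, was at 144 CPM in c11, 80.9 in c22 and 0.23 in c15, and Wnt5a was at 85.9 CPM in c11, 10.2 in c15 and 0 in c22. Tmem47, Fndc3c1, Ptger3, Piwil2 and Armcx2 completed the 10 widest ranges. With 1 library per line, these are values with no test. In the labels 2 of the 3 lines share their first number, and what they share is not stated, so the lines may not be independent of each other. The mock library lay outside the knockout range for 6849 of the tested genes (43.6%), where chance gives 50%.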

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

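The sums of pairs of knockout libraries were chosen after seeing the data: the planned sum of 2 lines could not be made as written, since the columns do not say which lines they are, so all 3 pairs were summed in turn. No paired analysis was possible because the groups share no replicate numbers. The medians of the glycolysis (-1.47 to -1.29), hypoxia response (-1.56 to -1.43) and stress response (1.37 to 1.48) lists kept their direction under all 18 alternatives and their side of the threshold under 16, and Hif1a (-0.81 to -0.09) under all 16. The exceptions were the other list tests: with an estimated correlation the adjusted p was 0.234 for glycolysis (-1.33), 0.161 for hypoxia response (-1.49) and 0.118 for the stress response (1.45), and with fry it was 0.147, 0.133 and 0.133. Scalings moved the median of all genes by at most 0.027. The count of called genes depended on the tool: DESeq2 called 51 higher and 67 lower, no filter gave 4 lower, and limma-voom, the legacy fit and each sum of 2 libraries gave 0 lower; without any 1 knockout library it was 0 lower. The cause was not tested, except that leaving out or summing libraries left fewer samples. Of the 20 named genes, all kept their direction, 19 passed under DESeq2 and Bnip3 also with no filter (adjusted p 0.0328). The count of genes that differed at least 4-fold among knockout libraries was 230 with a mean of at least 20 CPM, and 2669 at 2-fold, by construction. The medians of 5 lists that camera did not call changed sign, without a call, under these alternatives: extracellular matrix (-0.016 with upper quartile, -0.144 with limma-voom, -0.027 with c15 and c22 summed, -0.038 to 0.19 over single left-out libraries), mitochondrial genome transcripts (0.006 with c11 and c15 summed, -0.243 to 0.082 over left-out libraries), dendritic and mast cell markers (0.043 with no filter, -0.142 to 0.15 over left-out libraries, with too few genes to test without c15), neutrophil markers (-0.131 with a mean of at least 1 CPM, -0.019 to 1.011 over left-out libraries) and angiogenic ligands (-0.22 with limma-voom). A count of 0 in mock allowed up to 0.242 CPM, for counting error only.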

Other observations

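The tests of Gene Ontology processes, host-cell RNA, oxygen shortage, handling stress and chromosome 5 were chosen after the results were seen, and the splits were planned but read after them. Beyond the fixed lists, 1055 Gene Ontology processes of 15 to 300 genes, taken from the annotation in the deposited table, were tested with camera. Of these, 7 were called higher and 7 lower in the knockout libraries, and 0 with an estimated correlation. Genes of transport from the endoplasmic reticulum to the Golgi were higher as a group (87 genes, median log2 fold change 0.34, camera adjusted p = 2.71e-04, and adjusted p = 0.996 with an estimated correlation), with 46 above and 9 below mock in all 3 knockout libraries. The coat and tether genes Sec24d, Uso1 and Sec31a were examples, at log2 fold changes of 1.27 (SE 0.45), 1.28 (SE 0.36) and 0.79 (SE 0.38), and none passed over all genes. Genes of endoplasmic reticulum-associated degradation were higher too (47 genes, median 0.32, camera adjusted p = 5.08e-04, and adjusted p = 0.996 with an estimated correlation). Without members of the fixed stress, glycolysis and hypoxia lists, camera gave an unadjusted p of 7.94e-06 for transport (86 genes) and 7.28e-04 for degradation (44 genes). Both processes were picked from those called in the same libraries and lost only 1 and 3 genes. A small p was therefore likely in advance and is no separate check. Muscle contraction (29 genes, adjusted p = 5.08e-04, and adjusted p = 0.996 with an estimated correlation) was among the lower processes. In the same comparison, markers of macrophages (median -0.68), host fibroblasts (-0.80), muscle (-3.52) and erythroid cells (-2.83) were lower.

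The lower glycolysis and hypoxia response lists were weighed against RNA of host cells in the mock tumour, since muscle, erythroid and macrophage markers were also higher there. Host cells would bring their own abundant transcripts. All host-cell markers together exceeded the knockout mean by 822 CPM, against 16622 CPM for both lists, a ratio of 0.0494. The most abundant marker, Lyz2, accounted for 354 CPM. Glycolysis genes made up 13351 CPM of the excess of both lists, so this argues against host RNA as the whole source for the glycolysis list. The hypoxia response list was not weighed alone, and for that list the question stays open. Each library was then taken in turn as the lone one. The glycolysis median was -1.34 with mock alone and at most 1.04 from 0 in the other splits. In those splits mock was 1 of the 3 libraries on the other side, so they do not give a spread free of mock. Mock was not the furthest from 0 for every list. With c11 as the lone library, medians were 1.095 for macrophage, 2.192 for host fibroblast and 1.782 for osteoblast genes. With c22 they were 1.045 for immediate early and heat shock genes and -1.223 for interferon response genes. With mock these lists had medians of -0.684, -0.798, -0.793, -0.729 and 1.042. Also, 4 splits are too few for a share under 0.05. A loss of HIF-1 activity may account for the pattern, and so may a smaller oxygen shortage in the knockout tumours; the stress response list, which oxygen shortage also raises, had a median of 1.45, but glucose shortage raises it too, so these cannot be told apart. The state of a single mock tumour stays open as well.

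The higher stress response list might reflect handling stress when the tumours were taken. Of 14 immediate early and heat shock genes outside that list, 0 were above mock and 10 were below mock in all 3 knockout libraries, which argues against greater handling stress in the knockout tumours as the whole cause. With each library as the lone one, the median of the stress response list was 1.45 for mock and at most 0.53 from 0 for the others. Mock was again among the 3 libraries facing each knockout library, so these splits give no spread free of mock. Also, 4 splits are too few for a share under 0.05. Loss of HIF-1alpha and differences between the single mock tumour and the others were not tested apart.

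The stretch of chromosome 5 had the window of 11 neighbouring genes furthest from 0 in the genome (median -3.07). In 1000 shuffles of gene order the furthest window reached 1.85, so the permutation p was 0.001, the smallest they can give, which argues against a chance order of genes. Genes of the stretch outside the Abcb family had a median of -2.62. The stretch was bounded by fold changes, so a low median was set in advance and does not test for reads shared between Abcb1a, Abcb1b and Abcb4. It shows only that the lower genes were not confined to that family. A gain of the stretch in the mock cells, or its loss in the knockout lines, is a candidate explanation, but Cldn12 and Gtpbp10 upstream of it were lower too, and Dmtf1 inside it (-0.70) lay nearer 0 than its neighbours; copy number and regional regulation cannot be told apart from RNA of 1 mock library. In c22 the median log2 ratio to mock was 0.52 over 703 genes of chromosome 17, and in c15 it was -0.37 over 453 genes of chromosome 16.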
